A study of Oryza sativa Indica Group with 8 samples.

How the data were processed

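RNA from the roots of 14-day-old rice seedlings was measured on Affymetrix rice arrays in 4 groups of 2 biological replicates, 1 array each: WT, VC, OE and KD. The authors processed the arrays with GCOS and Affymetrix Expression Console 1.4.1.46; the summarization, background correction and normalization are not given in the sources used here. The deposited values are 1 value per probe set and array on the log2 scale, a scale checked on the hybridization spikes, whose lowest and highest concentrations differed by 5.89 units. The table holds 57381 probe sets. Control probe sets, 187 in number and including 64 for reporter genes, were left out of the tests, which leaves 57194.

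Array medians lay within 0.20 of each other, so the values were used as deposited, and quantile normalization was kept as an alternative. The medians, from 1.35 to 1.54, lay under the background limit given next, so this check says little about probe sets above background. Upper quartiles differed by up to 0.72. Signal at or under 1.72, the 95th percentile of 33 control probe sets for sequences from outside rice, was read as background. Probe sets were assigned to genes by the platform's gene identifiers: 22436 had 1 gene, 95 several and 34663 none, which gave 17905 genes, of which 2312 had a name beyond the locus. Gene names and the order of neighbouring genes came from a Japonica reference annotation, while the plants were Indica.

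Groups were compared in limma 3.58.1 (R 4.3.3), with all 8 arrays in 1 fit and Benjamini-Hochberg adjusted p under 0.05 over the 57194 probe sets. Log2 fold changes carry the SE of that fit, whose median was 0.15 with 7.05 total degrees of freedom. The fit pools the spread over groups, so the WT spread enters the SE of comparisons without WT. It also brings the lower spread of OE and KD into the SE of VC versus WT, which tends to make that SE too small. A fit of VC and WT alone, with fewer degrees of freedom, called 4212 probe sets, against 9375 in the pooled fit. The number of arrays and their spread limit the precision, and arrays have no read depth to report. The comparisons, their tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from 3 alternatives named in the closing section. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.

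Named genes were chosen by a rule. It took OsFBK1 and OsCCR14 where a table names them, which none did, so both are not analysed here. For each comparison it took the 10 genes with the largest log2 fold change in each direction, among probe sets with an adjusted p under 0.05, an absolute log2 fold change of at least 1, 1 gene and groups of arrays that do not overlap. It also took up to 3 members with the smallest p of each tested list. The text describes a selection of these, and genes outside the rule are named as chosen after their values were seen. Folds against a group at background were computed against the background limit and are given as at least that size.

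Gene lists were fixed as words in gene descriptions and as symbols. Only the symbols were applied, to gene symbols and synonyms, and 13 wrong matches were removed by hand. Of the 17905 genes, 2312 had a name beyond the locus. The gene numbers given for a list therefore count members with a matching symbol or synonym, not all measured genes of a family. Of the 42 lists, 31 had at least 3 measured genes and were tested with camera at a preset correlation of 0.01, with 1 probe set per gene (the highest mean) and Benjamini-Hochberg adjustment over 124 tests. Camera compares a list with other genes, so a list can be called lower with a median near 0 where most genes are higher. Camera with an estimated correlation and fry, which tests whether the genes of a list move 1 way, were alternatives. None of the 33 list calls held with an estimated correlation, and no called list's median changed sign under quantile normalization or median centring, though some changed size. The overlap of the OE and KD changes was set beside simulations of unchanged groups with shared controls.

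The steps were tested on simulated data in which 200 probe sets were changed between OE and VC. All simulated groups had the same spread, so the effect of unequal spread was not tested. Of these, 65% of the 2-fold and 99% of the 4-fold changes were recovered, 10 unchanged probe sets were called, and 0 were called by limma in the unchanged KD versus VC comparison. A shifted list was called by camera, and its adjusted p with an estimated correlation was 0.0260. Alternatives covered normalization, centring, a filter on dim probe sets, an intensity trend in the prior variance, the groups in the fit, the replicate number as a block, thresholds, 1 probe set per gene, array weights, the control group and each array left out in turn.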

Results

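The arrays were made to ask how raising or lowering OsFBK1, an F-box and kelch-repeat subunit of an E3 ubiquitin ligase, changes the transcriptome of rice roots. Roots of 14-day-old seedlings of the indica variety Pusa Basmati 1 were measured in 4 groups: the untransformed wild type (WT), a vector control (VC), an OsFBK1 over-expression line (OE) and an OsFBK1 knock-down line (KD). Each group had 2 biological replicates with 1 array each, so 8 arrays and 57194 probe sets were compared. Arrays have no read depth, and the number of arrays and their spread limit the precision. Values are on the log2 scale. A group mean at or under 1.72, the 95th percentile of 33 control probe sets for sequences from outside rice, was taken as background, and a gene at background in a group has only a bound on its fold change. No table given here names a probe set as OsFBK1, so the target gene is not analysed here and the OE and KD labels were not checked on it.

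The arrays of a group differed in how closely they matched. The replicate SD over all probe sets was 0.35 in WT, 0.12 in VC, 0.16 in OE and 0.18 in KD, and the correlation between replicates was 0.967 in WT and 0.992 or higher in the other groups. The 3′ minus 5′ signal difference, averaged over 3 control genes, is larger where RNA is more degraded. It was 4.15 and 4.07 in the WT arrays, 3.21 and 3.16 in VC, 3.57 and 3.90 in OE, and 4.13 and 3.91 in KD. The poly-A spike signal was 7.54 and 5.82 in WT, 5.35 and 5.05 in VC, 5.71 and 5.43 in OE, and 7.33 and 6.07 in KD. The mean upper quartile of the arrays was 2.97 in WT, 3.64 in VC, 3.65 in OE and 3.24 in KD.

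**Figure D1:**
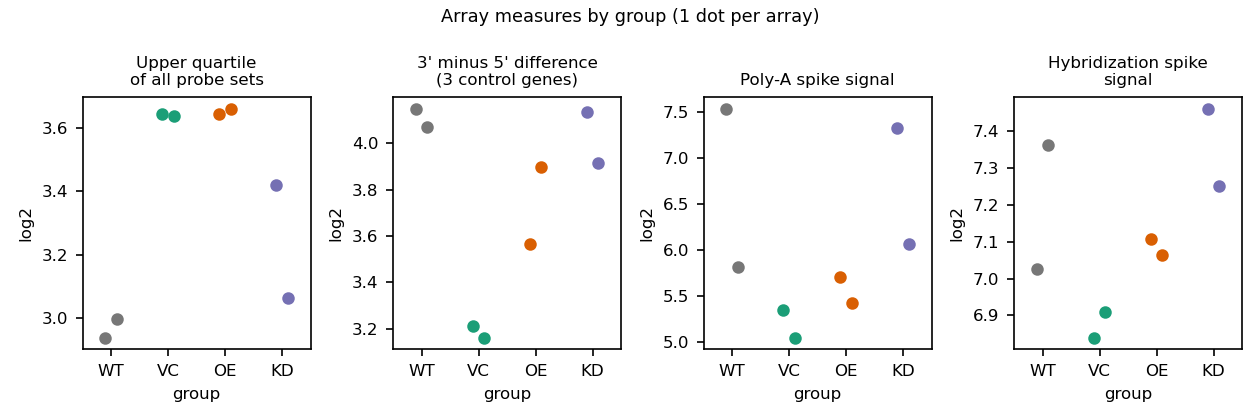
Array measures by group, 1 dot per array, each on a log2 scale (vertical axis): upper quartile of all probe sets, 3′ minus 5′ difference averaged over 3 control genes, poly-A spike signal and hybridization spike signal. The VC arrays have the smallest 3′ minus 5′ differences, 3.21 and 3.16, and the WT arrays the lowest upper quartiles, with a group mean of 2.97.

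The comparison of OE with VC asks what OsFBK1 over-expression changes against roots that carry the vector. AMY1.1, an alpha-amylase that breaks down starch, was at background in VC and at 7.66 ± 0.17 (SD, n = 2) in OE, at least 61.7-fold higher (limma adjusted p = 4.0e-05). PBZ1, a pathogenesis-related protein of the PR-10 family, had a log2 fold change of −3.95 ± 0.27 (SE, n = 2 arrays per group, as for all log2 fold changes here), and the jasmonate-signalling repressors JAZ10, JAZ11 and TIFY11A had −1.55 ± 0.14, −1.4985 ± 0.11 and −1.42 ± 0.11. The cyclin CYCB1-1 rose by 1.03 ± 0.10 and the replication licensing factor MCM2 by 0.98 ± 0.11.

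Further genes with large changes in OE were SPX2, of the SPX family of phosphate sensors, which rose by 2.50 ± 0.27, and CYP99A3, a cytochrome P450 of momilactone synthesis, at −2.41 ± 0.17. BURP10, a BURP-domain protein, and VLN4, a villin that bundles actin filaments, were at background in OE and at least 7.96-fold and 7.36-fold lower than in VC. RA14, a seed allergen, changed by −2.76 ± 0.12. RAB16C, a dehydrin induced by abscisic acid and drying, rose by 0.91 ± 0.13, and the expansin EXP1, which loosens cell walls, by 0.82 ± 0.10. Genes known here only by locus included LOC4328835, at 3.67 ± 0.20, LOC4352487, at −3.56 ± 0.16, LOC4334834, at background in OE and at least 12.85-fold lower, and LOC4340728, at background in OE and at least 38.0-fold lower than in VC.

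The cell cycle list, matched by symbol, held cyclin and MCM genes and no histones. Of its genes, 5 of 24 rose, 0 fell and 19 did not pass. CYCA2-1 rose by 1.24 ± 0.17, and MCM3 and CYCB2-2, chosen after their values were seen, by 1.05 ± 0.16 and 0.74 ± 0.11. With p adjusted over the list alone, 11 rose and 1 fell. The list was called higher than other genes (median log2 fold change 0.48, camera adjusted p = 0.000116), with adjusted p = 0.240 with an estimated correlation. Of the ribosomal proteins, matched by symbol, 1 of 22 rose (RPS15, 0.57 ± 0.10), 0 fell and 21 did not pass, and adjusted over the list alone 8 rose and 1 fell. The list's median was 0.21 (adjusted p = 0.00225, and adjusted p = 0.393 with an estimated correlation).

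Of the jasmonate synthesis and JAZ genes, 6 of 34 fell, 0 rose and 28 did not pass; adjusted over the list alone, 13 fell and 2 rose (median −0.22, adjusted p = 0.000374, and adjusted p = 0.240 with an estimated correlation). Of the pathogenesis-related genes, 3 of 11 fell, 0 rose and 8 did not pass; besides PBZ1 these were the chitinases Cht2, at −1.74 ± 0.20, and Cht9, at −0.78 ± 0.14. Adjusted over that list alone, 6 fell and 0 rose (median −0.56, adjusted p = 0.00223, and adjusted p = 0.259 with an estimated correlation). Of the monolignol pathway, which makes lignin precursors, 2 of 17 genes fell, 0 rose and 15 did not pass. Both encode cinnamyl alcohol dehydrogenases, CAD1 at −0.75 ± 0.11 and CAD3 at −0.66 ± 0.12. The counts adjusted over the list alone were 5 that fell and 0 that rose (median −0.24, adjusted p = 0.000385, and adjusted p = 0.308 with an estimated correlation).

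Of the ethylene synthesis and response factor genes, 1 of 12 fell (ERF24, −1.69 ± 0.19), 0 rose and 11 did not pass, and adjusted over the list alone 2 fell and 0 rose. The list's median was −0.23 (adjusted p = 0.0307, and adjusted p = 0.292 with an estimated correlation); without OE replicate 1 the adjusted p was 0.0842, and without dim probe sets, with 6 of the 12 genes above background, 0.0758. None of the 6 glutathione S-transferases passed in the limma fit over all probe sets, while adjusted over the list alone 3 fell and 0 rose (median −0.34, adjusted p = 0.00774, and adjusted p = 0.295 with an estimated correlation).

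In limma, 1024 of 57194 probe sets passed an adjusted p of 0.05 between OE and VC, 406 higher and 618 lower in OE, of which 132 and 292 changed at least 2-fold. The count was 15 without VC replicate 1, 13 without VC replicate 2, 30 without OE replicate 1, 83 without OE replicate 2, 438 without either KD array and 2717 without either WT array, and AMY1.1, LOC4334834, LOC4352487 and RA14 passed whichever array was left out. With WT in place of VC as the control, 6565 probe sets passed, 4848 of them higher in OE. LOC4334834 was at background in both OE and WT and no longer passed against WT. Of the 7 list calls, 3 were then kept, the ethylene, glutathione S-transferase and pathogenesis-related lists were no longer called, and the ribosomal protein list was called lower (adjusted p = 0.0154). Against their direction versus VC, ERF24 was higher in OE than in WT (adjusted p = 0.0232) and, chosen after their values were seen, Emp1, a late embryogenesis abundant protein, and LOC4342395 were lower (0.00536 and 0.0288). PBZ1, TIFY11A, CAD1, Cht2, LOC4352487 and RAB16C had estimates that changed sign against WT and did not pass (adjusted p from 0.0532 to 0.585). Calls lost against WT with the sign kept included CYP99A3 (log2 fold change −0.12), LOC4328835 (0.38), JAZ10 (−0.235), EXP1 (0.097) and RPS15 (0.074). After quantile normalization 6 of the 7 list calls were kept, without the ethylene list.

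**Figure D2:**
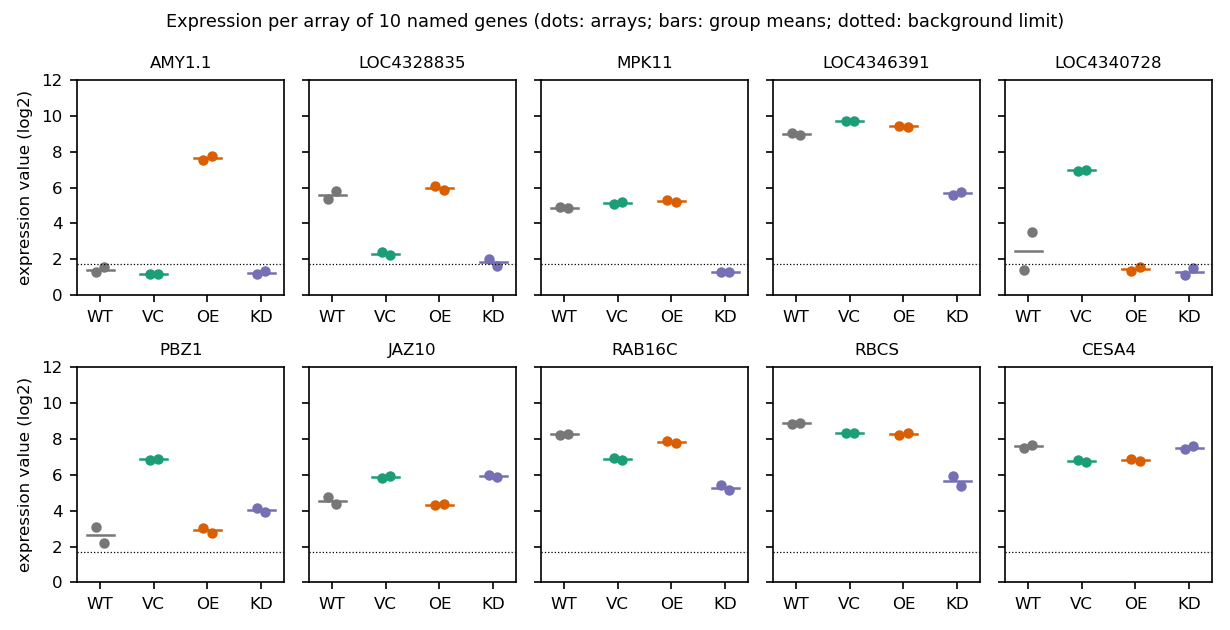
Expression per array (vertical axis, log2) of 10 named genes in the 4 groups; dots are arrays, bars are group means of 2 arrays and the dotted line is the background limit of 1.72. AMY1.1 lies above the limit in OE alone, MPK11 below it in KD alone, and PBZ1 averages 6.86 in VC and 2.90 in OE.

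The comparison of KD with VC asks what lowering OsFBK1 changes against the vector control. MPK11, a mitogen-activated protein kinase, was at 5.15 ± 0.07 (SD, n = 2) in VC and at background in KD, at least 10.8-fold lower (limma adjusted p = 6.9e-05). RBCS, the small subunit of Rubisco, changed by −2.69 ± 0.18 and PSAH, a subunit of photosystem I, by −1.61 ± 0.13. Photosynthesis genes were listed beforehand as a mark of green tissue carried over into root samples. A difference in carry-over was not told apart from a change within roots. The dehydrins RAB16C and RAB21 fell as well, at −1.61 ± 0.13 and −1.21 ± 0.14. The secondary-wall cellulose synthase genes CESA4, CESA7 and CESA9 rose by 0.73 ± 0.12, 0.74 ± 0.13 and 0.59 ± 0.12. Reporter probe sets differed between these lines: A was at 9.85 in VC and 3.004 in KD, B at 1.41 in VC and 9.74 in KD, and D at 1.64 in VC and 4.9985 in KD. OE was near VC for these, with A at 9.28, B at 1.47 and D at 1.36. Whether VC carries the vector of KD is not given in the sources used here. A difference between constructs was not told apart from an effect of lowering OsFBK1.

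LTP2-B, a lipid-transfer protein, rose by 2.22 ± 0.22 in KD. CIPK10, a kinase that acts with calcineurin B-like calcium sensors, changed by −2.76 ± 0.19, and VLN4 was at background, at least 7.36-fold lower than in VC. PBZ1 changed by −2.82 ± 0.27, JAZ11 by −1.17 ± 0.11 and CAD3 by −1.17 ± 0.12. The auxin-related genes SAUR39 and OsGH3-5 changed by −1.79 ± 0.25 and −1.42 ± 0.23. Genes known by locus included LOC4341274, which rose by 3.41 ± 0.10, LOC4346391, at −4.04 ± 0.10, LOC4327373, at background in KD and at least 8.53-fold lower than in VC, and LOC4340728, at background in KD and at least 38.0-fold lower.

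Of the photosynthesis genes, 4 of 5 fell, 0 rose and 1 did not pass; the others that fell were CAB2R, a chlorophyll-binding protein, at −1.13 ± 0.13, and PSAG, chosen after its value was seen, at −1.39 ± 0.20. Adjusted over the list alone, 4 fell and 0 rose (median −1.39, camera adjusted p = 0.00177, and adjusted p = 0.240 with an estimated correlation). Of the abscisic acid and dehydration genes, 3 of 6 fell, 0 rose and 3 did not pass, with RAB16D at −0.58 ± 0.11; adjusted over the list alone, 4 fell and 0 rose (median −0.62, adjusted p = 0.0115, and adjusted p = 0.292 with an estimated correlation). Of the pathogenesis-related genes, 3 of 11 fell, 0 rose and 8 did not pass, with the chitinases Cht2 at −1.54 ± 0.20 and Cht11 at −0.81 ± 0.15. Adjusted over the list alone, 6 fell and 0 rose (median −0.38, adjusted p = 0.0497, and adjusted p = 0.335 with an estimated correlation). That adjusted p was 0.0618 and 0.0563 without OE replicate 1 or 2, and 0.110 and 0.0605 without KD replicate 1 or 2. The 3′ minus 5′ difference, 4.13 and 3.91 in the KD arrays, was higher than the 3.21 and 3.16 of VC.

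All 3 secondary-wall cellulose synthases rose, also when adjusted over the list alone (median 0.73, adjusted p = 0.000733, and adjusted p = 0.240 with an estimated correlation). Of the expansins, 5 of 29 rose, 0 fell and 24 did not pass; EXPB6 rose by 0.91 ± 0.10, EXPB18 by 0.90 ± 0.14, EXP1 by 0.78 ± 0.10, and EXPB3 and EXP10, chosen after their values were seen, by 0.60 ± 0.10 and 0.57 ± 0.10. With p adjusted over the list alone, 8 rose and 0 fell (median 0.10, adjusted p = 0.000116, and adjusted p = 0.240 with an estimated correlation). Of the cyclin and MCM genes, 4 of 24 rose, 0 fell and 20 did not pass. Those that rose were CYCB1-1 by 1.09 ± 0.10, CYCA2-1 by 0.87 ± 0.17, CYCB2-2 by 0.75 ± 0.11 and MCM2, chosen after its value was seen, by 0.56 ± 0.11. The counts adjusted over the list alone were 4 that rose and 0 that fell (median 0.17, adjusted p = 0.000733, and adjusted p = 0.259 with an estimated correlation). Of the ribosomal proteins, 1 of 22 rose (RPS15, 0.49 ± 0.10), 2 fell (RPL18, −1.38 ± 0.13, and rpl5, −1.29 ± 0.16) and 19 did not pass, and adjusted over the list alone 6 rose and 3 fell. That list was called higher, with a median of 0.25 and a mean of 0.07 (adjusted p = 0.000126, and adjusted p = 0.335 with an estimated correlation). The symbols of RPL18, RPL27 and rpl5 are shared with plastid proteins, and the sources used here do not give the compartment. Without these 3 the list had 1 of 19 genes that rose, 0 that fell and a mean of 0.27 in KD versus VC.

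In limma, 2662 probe sets passed between KD and VC, 494 higher and 2168 lower in KD, of which 80 and 842 changed at least 2-fold; after quantile normalization 1792 passed, 883 higher and 909 lower. Over the probe sets above background the median log2 fold change was −0.23 as deposited and 0.01 after quantile normalization. The count was 153 without VC replicate 1, 132 without VC replicate 2, 1269 without KD replicate 1, 362 without KD replicate 2, 1246 without either OE array and 6383 without either WT array, while MPK11, LOC4346391, LOC4327373, LOC4341274, RBCS, PSAH, RAB16C, CIPK10 and VLN4 passed whichever array was left out. With WT in place of VC, 4145 probe sets passed, 2259 of them higher in KD. CIPK10, at a log2 fold change of −0.41 against WT, and VLN4, at background in both KD and WT, no longer passed. Of the 7 list calls, 3 were then kept, and the direction turned for the ribosomal protein (adjusted p = 0.0392), expansin (0.871), pathogenesis-related (0.901) and secondary-wall cellulose synthase (0.733) lists. PBZ1 and Cht11 were higher in KD than in WT (adjusted p = 0.0268 and 0.00456), against their direction versus VC. Estimates for Cht2, PSAG, LTP2-B, EXPB6, CESA4, CESA7 and RPS15 changed sign against WT and did not pass (adjusted p from 0.1105 to 0.996). Other calls lost against WT, with the sign kept, included CESA9 (log2 fold change 0.057), EXP1 (0.056) and JAZ11 (−0.10). After quantile normalization all 7 list calls were kept, and the medians of the expansins and of the cyclin and MCM genes went from 0.10 to 0.46 and from 0.17 to 0.47.

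The comparison of OE with KD sets the OsFBK1 lines against each other without the controls. Reporter probe sets differed here too, with A at 9.28 in OE and 3.004 in KD, B at 1.47 and 9.74, and D at 1.36 and 4.9985, and whether OE and KD carry the same vector is not given in the sources used here. AMY1.1 was at least 61.7-fold higher in OE than in KD, and MPK11, at background in KD, at least 11.68-fold higher (limma adjusted p = 4.4e-05 and 4.5e-05). The dehydrins RAB16C, RAB21 and RAB16B were higher in OE by 2.52 ± 0.13, 1.43 ± 0.14 and 1.34 ± 0.16. The photosynthesis genes RBCS, PSAH and CAB2R were higher in OE by 2.65 ± 0.18, 1.504 ± 0.13 and 0.97 ± 0.13. Carry-over of green tissue was not told apart from a change within roots here either. Lower in OE were CML31, a calmodulin-like protein, at −2.50 ± 0.34, and the jasmonate repressor JAZ10, at −1.60 ± 0.14.

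SPX2 was at background in KD and at least 5.77-fold higher in OE. By locus, LOC4328835 and LOC4346391 were higher in OE at 4.14 ± 0.20 and 3.75 ± 0.10, LOC4327373, at background in KD, at least 11.05-fold higher, and LOC4341274, LOC4325662 and LOC4340413 lower at −3.50 ± 0.10, −2.84 ± 0.14 and −2.67 ± 0.15. Of the abscisic acid and dehydration genes, 3 of 6 rose, 0 fell and 3 did not pass, and adjusted over the list alone 5 rose and 0 fell (median 0.87, camera adjusted p = 0.00480, and adjusted p = 0.292 with an estimated correlation). Of the photosynthesis genes, 3 of 5 rose, 0 fell and 2 did not pass, and adjusted over the list alone 4 rose and 0 fell (median 0.97, adjusted p = 0.00183, and adjusted p = 0.240 with an estimated correlation).

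Another 10 lists were called lower in OE than in KD relative to other genes, whose median above background was 0.20. Of the 3 secondary-wall cellulose synthases, CESA4 fell (−0.71 ± 0.12), 2 did not pass and, adjusted over the list alone, 3 fell (median −0.70, adjusted p = 0.000126, and adjusted p = 0.240 with an estimated correlation). Of 34 jasmonate genes, 4 fell, 1 rose and 29 did not pass, and adjusted over the list alone 7 fell and 1 rose (median −0.03, adjusted p = 0.000116, and adjusted p = 0.240 with an estimated correlation). Besides JAZ10, these were JAZ13, at background in OE and at least 2.63-fold lower, OsOPR5, of oxophytodienoate reduction, at −0.98 ± 0.12, and, chosen after their values were seen, TIFY11A at −0.83 ± 0.11 and the lipoxygenase LOX3 at 1.35 ± 0.19. Of 29 expansins, EXPB7 (−1.15 ± 0.12) and EXPB18 (−1.04 ± 0.14) fell and 27 did not pass, with 5 that fell adjusted over the list alone (median −0.04, adjusted p = 0.000733, and adjusted p = 0.240 with an estimated correlation). Of 17 monolignol genes, CAD8A (−0.91 ± 0.13) and 4CL5 (−0.61 ± 0.10) fell and 15 did not pass, with 2 that fell and 1 that rose adjusted over the list alone (median −0.16, adjusted p = 0.00337, and adjusted p = 0.385 with an estimated correlation). Of 6 glutathione S-transferases, GSTU6 fell (−0.93 ± 0.11) and 5 did not pass, with 2 that fell adjusted over the list alone (median −0.28, adjusted p = 0.00257, and adjusted p = 0.292 with an estimated correlation).

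NAC067 was the 1 of 8 NAC factors that fell (−0.85 ± 0.10), also adjusted over the list alone, with 7 that did not pass (median −0.09, camera adjusted p = 0.0497, and adjusted p = 0.347 with an estimated correlation). The adjusted p of that list was 0.163 without OE replicate 1 and 0.133 without KD replicate 1. The gene wrky38 was the 1 of 6 WRKY factors that fell (−0.97 ± 0.16), also adjusted over the list alone, with 5 that did not pass (median −0.39, adjusted p = 0.0497, and adjusted p = 0.343 with an estimated correlation). The adjusted p of the WRKY list was 0.0913 and 0.0966 without WT replicate 1 or 2, 0.136 without OE replicate 2 and 0.155 without KD replicate 1. None of 23 aquaporins passed, also adjusted over the list alone (median −0.09, adjusted p = 0.00327, and adjusted p = 0.292 with an estimated correlation). Only 3 of 16 diterpenoid phytoalexin genes averaged above background over the arrays. None of the 16 passed, with 1 that fell adjusted over the list alone (median −0.05, adjusted p = 0.00774, and adjusted p = 0.286 with an estimated correlation), and the call was lost when dim probe sets were left out (adjusted p = 0.107). None of 12 ethylene genes passed, with 2 that fell adjusted over the list alone (median −0.09, adjusted p = 0.0262, and adjusted p = 0.292 with an estimated correlation). The adjusted p of the ethylene list was 0.0748 without OE replicate 1 and 0.0822 without KD replicate 1.

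In limma, 847 probe sets passed between OE and KD, 652 higher and 195 lower in OE, of which 358 and 103 changed at least 2-fold; after quantile normalization 575 passed, 286 higher and 289 lower. Quantile normalization brought the median log2 fold change above background from 0.20 to 0.003. The count was 101 without OE replicate 1, 140 without OE replicate 2, 455 without KD replicate 1, 160 without KD replicate 2, 244 without either VC array and 3105 without either WT array. After quantile normalization 8 of the 12 list calls were kept, without the NAC, WRKY, diterpenoid phytoalexin and ethylene lists. The list medians that moved over 1.5 times became −0.15 for jasmonate, −0.17 for expansins, −0.27 for NAC, −0.13 for diterpenoid phytoalexin, −0.21 for ethylene, −0.65 for WRKY and −0.15 for aquaporin genes. AMY1.1, MPK11, RAB16C, RBCS, LOC4328835, LOC4346391, LOC4327373, LOC4341274, LOC4325662 and LOC4340413 passed whichever array was left out.

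**Figure D3:**
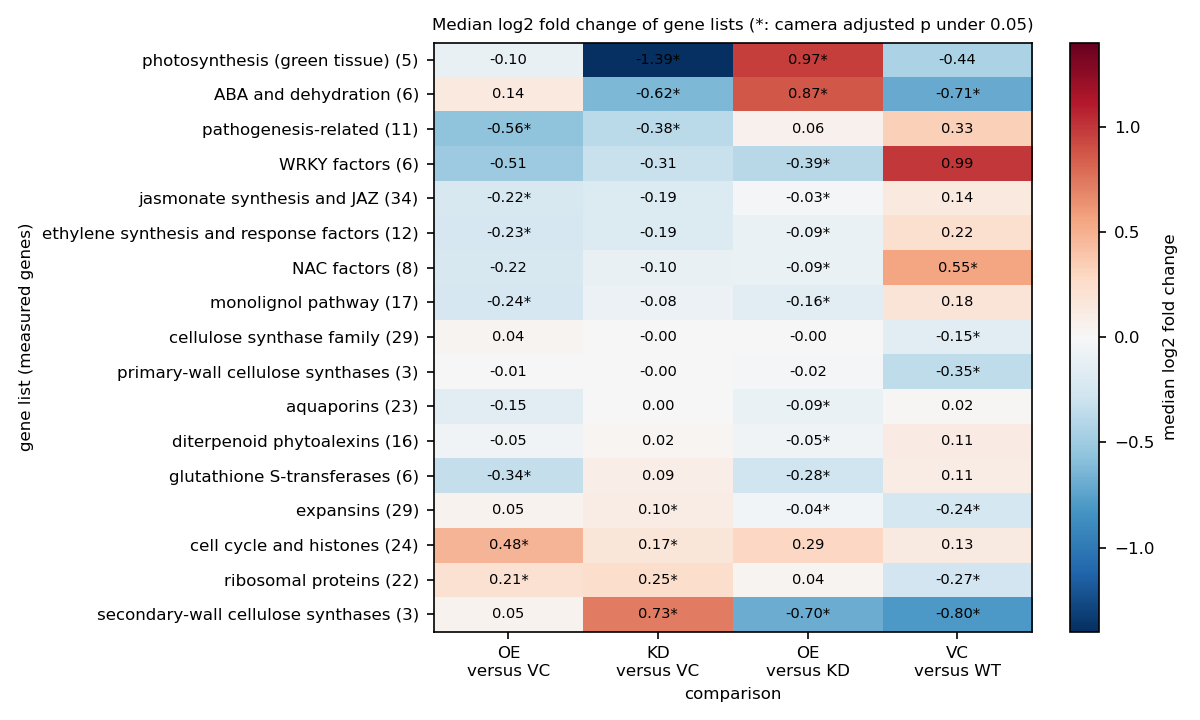
Median log2 fold change (colour and number) of the 17 gene lists called in at least 1 comparison (vertical axis, with the number of measured genes) in the 4 comparisons (horizontal axis); a star marks a camera adjusted p under 0.05 with the preset correlation. Photosynthesis is at −1.39 in KD versus VC, and the secondary-wall cellulose synthases are at 0.73 in KD versus VC and −0.80 in VC versus WT. The list labelled cell cycle and histones holds only cyclin and MCM genes.

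The comparison of VC with WT gives the difference between the control lines, against which the others are read. PBZ1 was higher in VC by 4.21 ± 0.27 (limma adjusted p = 0.00030), and the iron and nicotianamine transporter YSL13 by 3.21 ± 0.13. NIP2-1, a silicon channel of roots, was higher by 1.74 ± 0.10, the glutamine synthetase OsGS1;2 by 1.54 ± 0.14 and the nicotianamine aminotransferase NAAT1 by 1.28 ± 0.10. The small heat shock protein HSP16.9A was lower in VC at −3.53 ± 0.22 and LTP2-B at −2.82 ± 0.22. By locus, LOC4340728 and LOC4346960 were higher in VC by 4.51 ± 0.59 and 4.32 ± 0.18. The WT arrays of LOC4340728 were at 1.39, which is background, and 3.53, and its log2 fold change was 3.43 without WT replicate 1, while without WT replicate 2 it was at least 38.0-fold higher. LOC4352487, at background in WT, was at least 15.7-fold higher, and LOC4334834, also at background in WT, at least 12.85-fold higher. LOC4328835 was lower at −3.30 ± 0.20 and LOC9268400 at −3.04 ± 0.12.

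Of the NAC factors, 3 of 8 rose, 0 fell and 5 did not pass: NAC067 by 1.51 ± 0.10, NAC048 by 0.83 ± 0.11 and NAC071 by 0.55 ± 0.12. Adjusted over the list alone, 5 rose and 0 fell (median 0.55, camera adjusted p = 0.0497, and adjusted p = 0.348 with an estimated correlation). That adjusted p was 0.0860 without dim probe sets, 0.203 without WT replicate 2, 0.0618 without VC replicate 2, 0.0554 and 0.0504 without OE replicate 1 or 2, and 0.0585 and 0.0530 without KD replicate 1 or 2. Of the abscisic acid and dehydration genes, 4 of 6 fell, 0 rose and 2 did not pass: RAB16C (−1.37 ± 0.13), LEA19 (−1.27 ± 0.13), RAB21 (−0.79 ± 0.14) and, chosen after its value was seen, RAB16B (−0.63 ± 0.16). Adjusted over the list alone, 5 fell and 0 rose (median −0.71, adjusted p = 0.00130, and adjusted p = 0.259 with an estimated correlation). Of the ribosomal proteins, 5 of 22 fell, 0 rose and 17 did not pass: rps20 (−0.63 ± 0.11), RPS26 (−0.58 ± 0.12), RPS15 (−0.50 ± 0.10) and, chosen after their values were seen, RPL30 (−0.47 ± 0.12) and RPL39B (−0.47 ± 0.12). With p adjusted over the list alone, 9 fell and 0 rose (median −0.27, adjusted p = 7.34e-06, and adjusted p = 0.292 with an estimated correlation).

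All 3 secondary-wall cellulose synthases fell, CESA7 at −0.90 ± 0.13, CESA4 at −0.80 ± 0.12 and CESA9 at −0.54 ± 0.12, also when adjusted over the list alone (median −0.80, camera adjusted p = 0.00559, and adjusted p = 0.259 with an estimated correlation). Of the 3 primary-wall cellulose synthases, CESA1 fell (−0.54 ± 0.10) and 2 did not pass, with 2 that fell adjusted over the list alone (median −0.35, adjusted p = 0.0497, and adjusted p = 0.449 with an estimated correlation). That adjusted p was 0.101 and 0.109 without WT replicate 1 or 2, 0.0795 without VC replicate 2, 0.0529 without OE replicate 1, and 0.0566 and 0.0511 without KD replicate 1 or 2. In the cellulose synthase family of 29 genes, 7 fell, among them CSLF6 (−0.81 ± 0.10), 5 rose and 17 did not pass; adjusted over the list alone, 11 fell and 7 rose. The 5 that rose, chosen after their values were seen, were CSLC2 (1.03 ± 0.18), CSLH1 (1.00 ± 0.20), CSLE2 (0.60 ± 0.14), CSLA5 (0.57 ± 0.11) and LOC4341571, at background in WT and at least 1.14-fold higher in VC. The list was called lower (median −0.15, adjusted p = 0.0283, and adjusted p = 0.286 with an estimated correlation), with an adjusted p of 0.0881 without WT replicate 2. Of the expansins, 7 of 29 fell, among them EXPB2 (−1.07 ± 0.12) and EXPB6 (−1.02 ± 0.10), 19 did not pass and 3 rose: EXP7 (1.13 ± 0.14) and, chosen after their values were seen, EXPL2 (1.31 ± 0.32) and EXPB7 (0.82 ± 0.12). Adjusted over the list alone, 10 fell and 3 rose (median −0.24, adjusted p = 0.00325, and adjusted p = 0.240 with an estimated correlation).

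In limma, 9375 probe sets passed between VC and WT, 6701 higher and 2674 lower in VC, of which 3366 and 479 changed at least 2-fold; 758 of the 9375 had both groups at background. After quantile normalization 7495 passed, 4202 higher and 3293 lower, and the median log2 fold change above background went from 0.30 to 0.05. Of the 7 list calls, 5 were then kept, without the NAC and primary-wall cellulose synthase lists, and the median of the cellulose synthase family went from −0.15 to −0.28. The 3′ minus 5′ difference and the poly-A spike signal were higher in WT than in VC, and the WT replicate SD of 0.35 was above the 0.12 of VC. The count was 14898 without WT replicate 1, 15741 without WT replicate 2, 2938 without VC replicate 1 and 2818 without VC replicate 2.

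**Figure D4:**
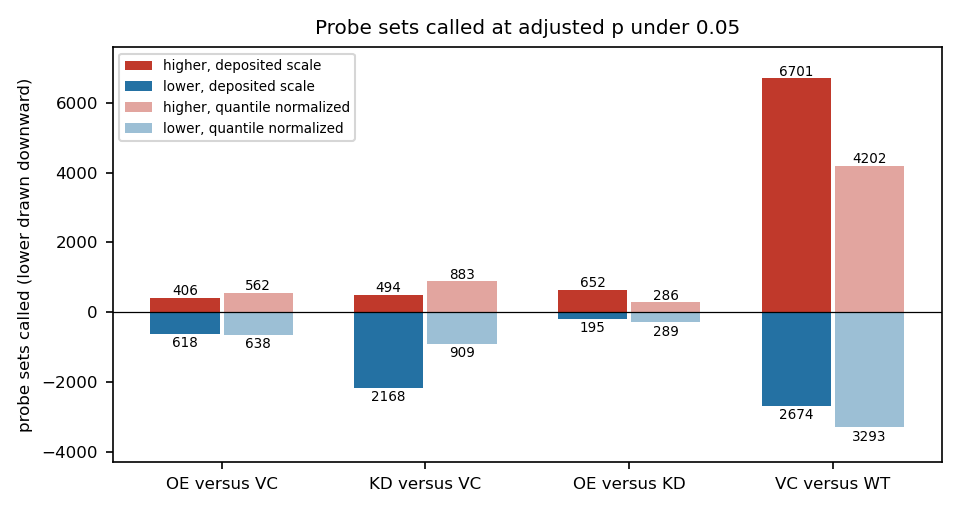
Probe sets with an adjusted p under 0.05 (vertical axis, lower calls drawn downward) in the 4 comparisons (horizontal axis), as deposited (dark bars) and after quantile normalization (pale bars). Lower calls outnumber higher ones in KD versus VC as deposited, 2168 against 494, and not by much after quantile normalization, 909 against 883.

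The changes of OE and KD against VC had probe sets in common. Of those called in both, 226 were higher in OE and KD, 365 were lower in both and 18 went opposite ways, where independent lists of these sizes would share 3.51 higher and 23.4 lower. JAZ11, PBZ1, VLN4, Cht2 and CAD3 were lower in both lines, and CYCB1-1, CYCA2-1, MCM2, EXP1 and RPS15 higher in both. Because both comparisons use the same VC arrays, unchanged groups were simulated 20 times against shared controls. At an unadjusted p under 0.05, 3775 probe sets changed in 1 direction in both lines, against a simulated mean of 647.8 (603 to 714), and the correlation of fold changes was 0.544, against 0.499. The simulations gave every array of a probe set the same spread, which sets their correlation near 0.499 whatever the data. The replicate SD was 0.12 in VC, 0.16 in OE and 0.18 in KD, so that correlation decides nothing. Simulated probe sets were also drawn independently, so 603 to 714 is too narrow a range for genes that vary together. The covariance was 0.0514 observed and 0.00906 simulated, a difference of 0.0424. The number shared in 1 direction was 591 with all arrays, 9 without either VC array, 16 and 41 without OE replicate 1 or 2, 185 and 95 without KD replicate 1 or 2, and 1681 without either WT array. With WT as the control of OE the shared calls were 56 higher and 219 lower, where independent lists would share 41.9 and 65.1. Another 803 went opposite ways and the correlation of fold changes was −0.308. With WT as the control of KD the shared calls were 46 higher and 44 lower, where independent lists would share 16.0 and 20.4. Another 279 went opposite ways and the correlation was −0.0903. Opposite calls outnumbered shared ones under both, while shared calls stayed above the independent numbers. No independent number was computed for these opposite calls.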

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

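The tests of hybridization spikes, of slopes within replicate pairs, of VC above WT and of the median shift from each WT array were chosen only after the results were seen.

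Reporter probe sets stand for genes used in constructs and were outside the comparisons. Of 64, 4 had both arrays of a transgenic line above both WT arrays, with a mean above background and at least 2-fold above that of WT, and 60 did not. Reporter probe set A was at 9.85 in VC, 9.28 in OE and 3.004 in KD, against 1.80 ± 0.51 (SD, n = 2) in WT. Reporter probe set B was at 9.74 in KD, against 1.27 ± 0.08 in WT. Reporter probe set C was at 8.32 in VC, 7.40 in OE and 7.96 in KD, against 2.13 ± 1.04 in WT. Reporter probe set D was at 4.9985 in KD, against 1.49 ± 0.25 in WT.

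The 365 probe sets lower in both OE and KD than in VC were a median of 1.22 above WT in VC, and 0.19 and 0.17 above WT in OE and KD. With a different VC array as the control of each line, fold changes still had a mean correlation of 0.523 over all probe sets above background. That set is wider than the 365, and genes are not independent replicates. The value argues against chance values of single VC arrays as the whole source of that correlation. Anything that the 2 VC arrays share stays in both fold changes. RNA quality cannot be told apart from the VC line: the 3′ minus 5′ difference was 3.21 and 3.16 in VC and 3.57 to 4.15 in all other arrays, WT included. The slope per unit of that difference was 0.11 within the OE and KD pairs and −1.45 between the groups, for probe sets selected as lower than in VC. Over all probe sets above background the slopes were 0.17 and −0.17. These slopes rest on 2 replicate pairs and do not decide. The pattern may reflect a VC line that lies above WT for these genes. Their selection fixes that OE and KD lie below VC but not where WT lies. By the median, WT was within 0.19 of both lines and 1.22 below VC. Single probe sets of the 365 did differ from WT: 94 were called above and 29 below it in OE, and 83 above and 34 below in KD. In VC these numbers were 334 and 13. An effect of OsFBK1 level shared by both lines was not tested and stays open, as does the history of the VC line or its plants, and part of the overlap may come from the shared VC arrays.

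Of the calls between VC and WT, 71.5% were higher in VC. A uniform difference in array brightness is argued against by the hybridization spikes, which changed by a mean of −0.32 while genes above background rose by a median of 0.30, with 1 of 18 spikes moving with the genes. A single WT array is argued against by the median shift above background, 0.27 and 0.31 without WT replicate 1 or 2 against 0.30; the 8332 and 9053 higher calls (6701 with both) decide nothing, since lower calls rose from 2674 to 6566 and 6688 and the share of higher calls was 55.9% and 57.5%. Slopes within replicate pairs were 0.0151 per unit of poly-A signal and 0.22 per unit of hybridization spike signal, against −0.68 and −3.13 between the groups. These slopes are over probe sets called higher in VC, a selection that sets the sign of the slopes between groups and adds to their size. Over all probe sets above background they were 0.0085 and 0.18 within pairs and −0.20 and −0.94 between groups. The 2 pairs with enough spread, WT and KD, had slopes of −0.022 and 0.065 for poly-A signal there. For hybridization spikes they had 0.11 and 0.39. Neither pair came near the slopes between groups, which argues against RNA yield and labelled amount as the whole cause. With only 2 pairs, neither is excluded. Scaling between arrays cannot be told apart from a change in many genes: quantile normalization brought the share to 56.1%, and equal distributions pull shares toward even whatever the source, while the difference between the lines also stays open.

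Of the calls between KD and VC, 81.4% were lower in KD. Uniform brightness is argued against by the hybridization spikes, which changed by 0.48 while genes above background had a median of −0.23, with 0 of 18 spikes moving with the genes. Slopes within replicate pairs were 0.0031 per unit of poly-A signal and 0.17 per unit of hybridization spike signal, against −0.60 and −1.85 between the groups, on 2 pairs with enough spread. These slopes are over probe sets called lower in KD. Over all probe sets above background they were 0.0085 and 0.18 within pairs and −0.15 and −0.47 between groups. Scaling cannot be told apart from a change in many genes here either: the share of lower calls after quantile normalization was 50.7%, in a test whose outcome equal distributions largely fix. An effect of OsFBK1 stays open and was not tested.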

How the results depend on the processing

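The WT arrays left out of the fit, calls above the background limit in either group, and the ribosomal list without RPL18, RPL27 and rpl5 were alternatives chosen after seeing the data; all others were chosen before. The cause was not tested for any change below unless stated.

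Counts of changed probe sets are given for OE versus VC, KD versus VC, OE versus KD and VC versus WT, with 1024, 2662, 847 and 9375 as reported. Array weights gave 3865, 7147, 2146 and 6585, with weights of 0.339 for WT and 2.24 for VC. Fits of only the 2 groups compared gave 3191, 5377, 645 and 4212. The WT arrays left out of the fit gave 2717, 6383 and 3105 for the first 3. An intensity trend gave 1908, 3269, 1001 and 10566, and 1 probe set per gene 1412, 2532, 946 and 6113, with fewer features tested. Adding a 2-fold threshold gave 424, 922, 461 and 3845, and an unadjusted p with a 2-fold change 577, 1203, 724 and 4317. WT in place of VC gave 6565 and 4145, and VC and WT averaged as control 1621 and 1459. Quantile normalization, median centring and the filter on dim probe sets stayed within 1.5 times of each count, as did the 8617 calls above background between VC and WT.

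With 1 array left out, counts ranged from 13 to 2717, 132 to 6383, 101 to 3105 and 2818 to 15741, and shared calls of OE and KD from 9 to 1681. A group with a lone array is assumed to vary like the other groups. Shared calls, 591 as reported, were 275 with WT as the control of OE (803 opposite, correlation −0.308), 90 with WT as the control of KD (279 opposite, −0.0903), 1176 with an intensity trend, 1648 with only the 2 groups compared, 2249 with array weights and 1681 with the WT arrays left out. With the replicate number as a block (replicate block), the counts were 507, 1763, 505 and 8230, and shared calls 284; replicate numbers do not pair samples, as correlations of residuals between groups ran from −0.045 to 0.081.

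Lists called numbered 7, 7, 12 and 7. Camera with an estimated correlation called 0, 0, 0 and 0, fry 17, 15, 10 and 25, and WT in place of VC 12 and 8, of which 3 and 3 were also called in the same direction against VC. Quantile normalization called 7, 7, 8 and 5, and ended the calls of ethylene genes in OE versus VC, of NAC, WRKY, diterpenoid and ethylene genes in OE versus KD, and of NAC and primary-wall cellulose synthase genes in VC versus WT. With 1 array left out the numbers ranged from 7 to 9, 6 to 7, 9 to 12 and 5 to 8. Each of the 33 list calls was lost in at least 1 alternative. Without RPL18, RPL27 and rpl5 the ribosomal list kept its calls (adjusted p = 6.87e-05 in OE versus VC, 1.445e-07 in KD versus VC and 1.87e-06 in VC versus WT). With WT in place of VC, 5 lists turned direction. The adjusted p was then 0.0154 for ribosomal proteins in OE (alternatives 6.87e-05 to 0.393), 0.0392 for ribosomal proteins in KD (1.445e-07 to 0.335), 0.871 for expansins in KD (2.98e-05 to 0.871), 0.901 for pathogenesis-related genes in KD (0.00518 to 0.901) and 0.733 for secondary-wall cellulose synthases in KD (0.000632 to 0.733).

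Of 146 pairs of a named gene and a comparison, 104 lost the call in at least 1 alternative and 21 reversed. Without VC replicate 1 or 2, 91 and 95 lost it; quantile normalization ended 10 calls and the filter on dim probe sets 0. Named calls in OE and KD with WT in place of VC were kept in 29 pairs, lost with the sign unchanged in 23 and reversed in 21. WT in place of VC reversed these log2 fold changes in OE: PBZ1 0.26, LOC4352487 0.50, BURP10 0.0936, VLN4 0.14, TIFY11A 0.42, CAD1 0.10, Cht2 0.37, ERF24 0.92, RAB16C −0.46, Emp1 −0.86 and LOC4342395 −0.82. In KD it reversed LTP2-B −0.60, PBZ1 1.39, CESA4 −0.0707, CESA7 −0.15, EXPB6 −0.11, RPS15 −0.0012, PSAG 0.65, Cht2 0.57, Cht11 1.21 and AGP1 −0.23. Of these 21 values, 5 passed against WT: ERF24, Emp1 and LOC4342395 in OE, and PBZ1 and Cht11 in KD. BURP10 and VLN4 were at background in both OE and WT, so their direction against WT is not read. WT was at background for LOC4352487, ERF24 and Cht11, which were at least 1.33-fold, 1.42-fold and 2.09-fold higher than WT. VC and WT averaged as control reversed Cht11 in KD, at 0.20. OsFBK1 expression has no value under any alternative, since no table names its probe set. Signal over background limits the folds given as at least a size.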

Other observations

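The counts of neighbouring genes were planned before their result was seen; genes named here outside the rule were chosen after their values were seen.

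Of the 18 probe sets called in opposite directions in OE and KD against VC, 17 were higher in OE and lower in KD, where independent lists would share 15.4, and 1 went the other way, where they would share 5.34; these numbers leave out the shared VC arrays. Besides RAB16C, they included Emp1, a late embryogenesis abundant protein, with a log2 fold change of 1.51 ± 0.11 (SE, n = 2 arrays per group) in OE and −0.94 ± 0.11 in KD, and LOC4342395, at 1.198 ± 0.18 and −2.03 ± 0.18. WT was above all 3 other groups for Emp1, at 6.90, against 4.52 in VC, 6.04 in OE and 3.59 in KD. LOC4340413 was the 1 that went the other way, at −1.25 ± 0.15 in OE and 1.43 ± 0.15 in KD.

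Between VC and WT, 11 of 24 iron acquisition genes rose and 1 fell, among them YSL13 and NAAT1, and 9 of 22 auxin transport and response factor genes rose and 1 fell. Neither list was called by camera (adjusted p = 0.373 and 0.488). In that comparison 5 of 26 Aux/IAA repressors rose and 1 fell, 5 of 10 SAUR and GH3 genes and 5 of 15 phosphate starvation genes rose, 4 of 15 nitrogen genes rose and 2 fell, 4 of 18 cytokinin genes rose and 1 fell, 5 of 43 heat shock genes rose and 3 fell, and 7 of 29 cytochrome P450 genes rose and 1 fell. Of the MYB factors 2 of 6 rose, of the hypoxia genes 2 of 6, of the laccases 1 of 9, with 1 that fell, and of the glutelin and oleosin genes 1 of 5. None of these 13 lists, nor the 3 xylan synthesis genes, of which 0 passed in any comparison, was called by camera in any comparison. In OE versus VC, KD versus VC and OE versus KD, at most 3 genes of any of them passed in either direction.

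Lists with fewer than 3 measured genes were not tested. The class III peroxidase PRX74 rose by 0.82 ± 0.10 in OE and 0.94 ± 0.10 in KD against VC, and was at −0.80 ± 0.10 in VC against WT. The arabinogalactan protein AGP1 rose by 0.52 ± 0.10 in KD against VC and was at −0.75 ± 0.10 in VC against WT, and the Casparian strip protein OsCASP1 was at −0.56 ± 0.14 and the gibberellin oxidase GA20OX3 at 0.78 ± 0.12 in VC against WT. PRX112 and XTH8 did not pass in any comparison, and CCR1 and GA20OX2 were at background in all 4 groups. The symbols set for F-box and kelch proteins, SKP1 and cullin, and wall-associated kinases matched no measured gene, and most measured genes have no name beyond the locus. Proteasome subunits and pectin modification had words but no symbols, so they were not searched. Whether the arrays measure genes of these families was therefore not examined.

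A local change of the chromosome in a line might alter neighbouring genes together, so pairs of neighbouring measured genes that both passed and changed at least 2-fold in 1 direction were counted against 10000 random draws. There were 9 pairs in OE versus VC (95th percentile of draws 5, highest 10, permutation adjusted p = 0.0016), 12 in KD versus VC (15, 23, 0.239), 8 in OE versus KD (6, 11, 0.0108) and 223 in VC versus WT (198, 230, 0.0016). The KD versus VC count lay within the draws, whose mean was 9.41. It decides nothing there, since a local change that adds few pairs would not stand out. In the other comparisons a local change cannot be told apart from gene families in tandem, which the draws ignore: pairs of TIFY11A, JAZ11 and JAZ10 and of RAB16C, RAB16B and RAB21 were among them.

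Of the 80 genes taken by the rule for the largest changes, counted per comparison, 22 had another probe set. For 14 of these no other probe set was called the same way, among them LTP2-B in KD versus VC and in VC versus WT, and for 1 another was called the other way.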
